A study of Homo sapiens with 8 samples.

How the data were processed

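Gene expression was measured on 8 Affymetrix human 3' expression arrays with the HG-U133 Plus 2.0 probe sets, 2 for each of 4 groups of BEAS-2B cells. BEAS-2B is an established human bronchial epithelial cell line. Per the labels' protocols, the cells were kept for 24 h in supplement-free medium and treated for 3 h, and biotinylated cRNA was prepared from 250 ng of total RNA with a 3' amplification kit. The groups were vehicle control (1% DMSO and 4% sodium acetate), 100 nM elastase with 1% DMSO, 100 nM elastase with 10 µM symplostatin 5, and 10 µM symplostatin 5 with the elastase vehicle. The sample titles name DMSO for the control and elastase groups, and not for either group with symplostatin 5. The labels call the 2 arrays of a group biological duplicates, and they were treated as separate samples.

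The deposited table holds log2 expression values of 54675 probe sets, between 1.67 and 14.33. The authors' background correction, summarization and normalization are not given in the sources used here. Per the submitters' processing notes, limma was used, with no version given. The array medians lay between 4.10 and 4.19, so the values had been brought to a common level before deposit, and they were used as deposited. No scanner files were used here. The number of arrays limits the precision of every value.

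Probe sets were named through the platform annotation. Of the 54675 probe sets, 41097 had 1 gene symbol, 1801 had several, and 11721 that are not control probe sets had none. The 62 control probe sets were left out, 6 of which carried a symbol. For 41043 probe sets the symbol was looked up through the Entrez gene number in RefSeq (GRCh38.p14), which changed 0 symbols. This table was also the source of the class of each gene (protein coding, lncRNA or pseudogene). It gave no coordinates here, since the files name no build. For each gene the probe set with the highest mean over the 8 arrays was kept, which left 19775 genes, of which 10523 had more than 1 probe set.

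A group-means model was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with default settings), which leaves 4 residual degrees of freedom and added 3.6 prior ones. All 6 contrasts were tested two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each contrast. A gene was called changed at an adjusted p under 0.05. The interaction is the elastase effect with symplostatin 5 minus the elastase effect without it. Log2 differences are given with limma's moderated standard error (SE), and group levels as the mean ± SD of 2 arrays.

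Before the data were examined, 28 gene lists with 656 members were fixed, of which 596 were measured: inflammatory cytokines and chemokines, NF-kappaB regulators and targets, immediate early genes, EGFR ligands and ERK output, YAP and TEAD targets, SRF and MRTF targets, extracellular matrix and adhesion, proteases with their inhibitors and receptors, mucins, p53 targets, apoptosis regulators, G1/S, G2/M, the unfolded protein and integrated stress response, heat shock, NRF2 targets, TGF-beta and BMP targets, FOXO targets, sterol synthesis, hypoxia targets, interferon response, histones, markers of basal, secretory and ciliated, fibroblast, leukocyte and endothelial cells, and reference genes. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the arrays, and with fry. The adjustment was over the 28 lists of a contrast.

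The share of the elastase effect left with symplostatin 5 was the least-squares slope through 0, over the genes called in elastase vs control, of the difference between elastase plus symplostatin 5 and symplostatin 5 on the difference between elastase and control. These differences share no array. Comparisons that do share control or elastase arrays were set beside 100 simulated sets of unchanged groups. For a gene list, the median expected of an unchanged group was the list's median in the first comparison times the simulated slope between the comparisons, 0.5 or -0.5. The simulated sets held no treatment effect, so such values take the whole first difference as noise.

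The genes named were chosen by a rule written before the data were examined: in each comparison of a treated group with control, and of the combination with elastase, the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap, up to 4 called members of each list, and CXCL8, IL6, IL1A, IL1B, ICAM1, CCL2, CCN1, CCN2, HBEGF, FOS, EGR1, MUC1 and CDKN1A whatever their values. Some further genes that the rule held are not reported here. Members of lists, and genes of the interaction, that lie outside this rule were named after their values were seen.

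The fit was tested on simulated data with the means and variances of the 19775 genes in elastase vs control, 5 times with 200 changed genes of 4 sizes. limma recovered 65.2% of the genes changed 1.5-fold, 98.8% of those changed 2-fold, and 100% of those changed 3-fold and 4-fold, and called 0.0388% of the unchanged genes. camera called the shifted list in 5 of 5 runs and 0 of 135 unshifted lists. The simulated genes varied independently, while the correlation estimated from the arrays was 0.19 for FOXO targets in elastase vs control. The 0 of 135 therefore does not test for false calls among correlated genes.

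The alternatives, whose effect is given in the closing section, were a filter keeping the upper 50% of genes by mean, all probe sets tested, the mean of a gene's probe sets, quantile normalization, centring on the median, eBayes with trend and robust settings, array weights, a fit on the compared groups alone, the replicate number as a block, a minimum of 1.5-fold, an adjusted p under 0.01, a floor at the 20th percentile, and leaving out each array in turn. Fits without both symplostatin 5 arrays, the slope over protein-coding genes and a split estimate on the genes with the lowest p were added after seeing the data.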

Results

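Transcript levels were measured in BEAS-2B human bronchial epithelial cells 3 h after treatment with human neutrophil elastase, a serine protease that neutrophils release in inflamed airways, with symplostatin 5, a cyclic depsipeptide elastase inhibitor from marine cyanobacteria, with the combination, or with vehicle. Each of the 4 groups had 2 arrays. Correlations over genes between the 2 arrays of a group lay between 0.99683 and 0.99756, and those between arrays of different groups between 0.99481 and 0.99763. The first principal component, with 30.5% of the variance, placed the symplostatin 5 arrays at 21.3 and 14.8 and the control arrays at -13.2 and -8.01. The second, with 17.8%, placed the elastase arrays at -12.6 and -14.9 and the control arrays at 13.9 and 5.03. The symplostatin 5 arrays also had the narrowest signal distributions, with interquartile ranges of 3.66 and 3.69 on the log2 scale against 3.79 and 3.82 in control.

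The first comparison asked what elastase alone does to the cells. Transcripts of the cytokines IL1B, IL6 and IL1A and of the monocyte chemoattractant CCL2 rose with elastase. IL1B was 2.91-fold higher, at a log2 level of 7.58 ± 0.013 with elastase and 6.04 ± 0.015 in control (mean ± SD, n = 2). IL6 was 2.26-fold higher, at 9.24 ± 0.058 against 8.07 ± 0.080 (n = 2), and IL1A and CCL2 rose 1.85-fold and 1.89-fold. HES1, a transcriptional repressor that Notch signalling induces, rose 2.98-fold, from 6.45 ± 0.14 to 8.03 ± 0.011 (n = 2). The adjusted p from limma was 0.0082 for HES1, 0.0085 for IL6, 0.012 for IL1B, 0.021 for IL1A and 0.031 for CCL2.

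**Figure D1:**
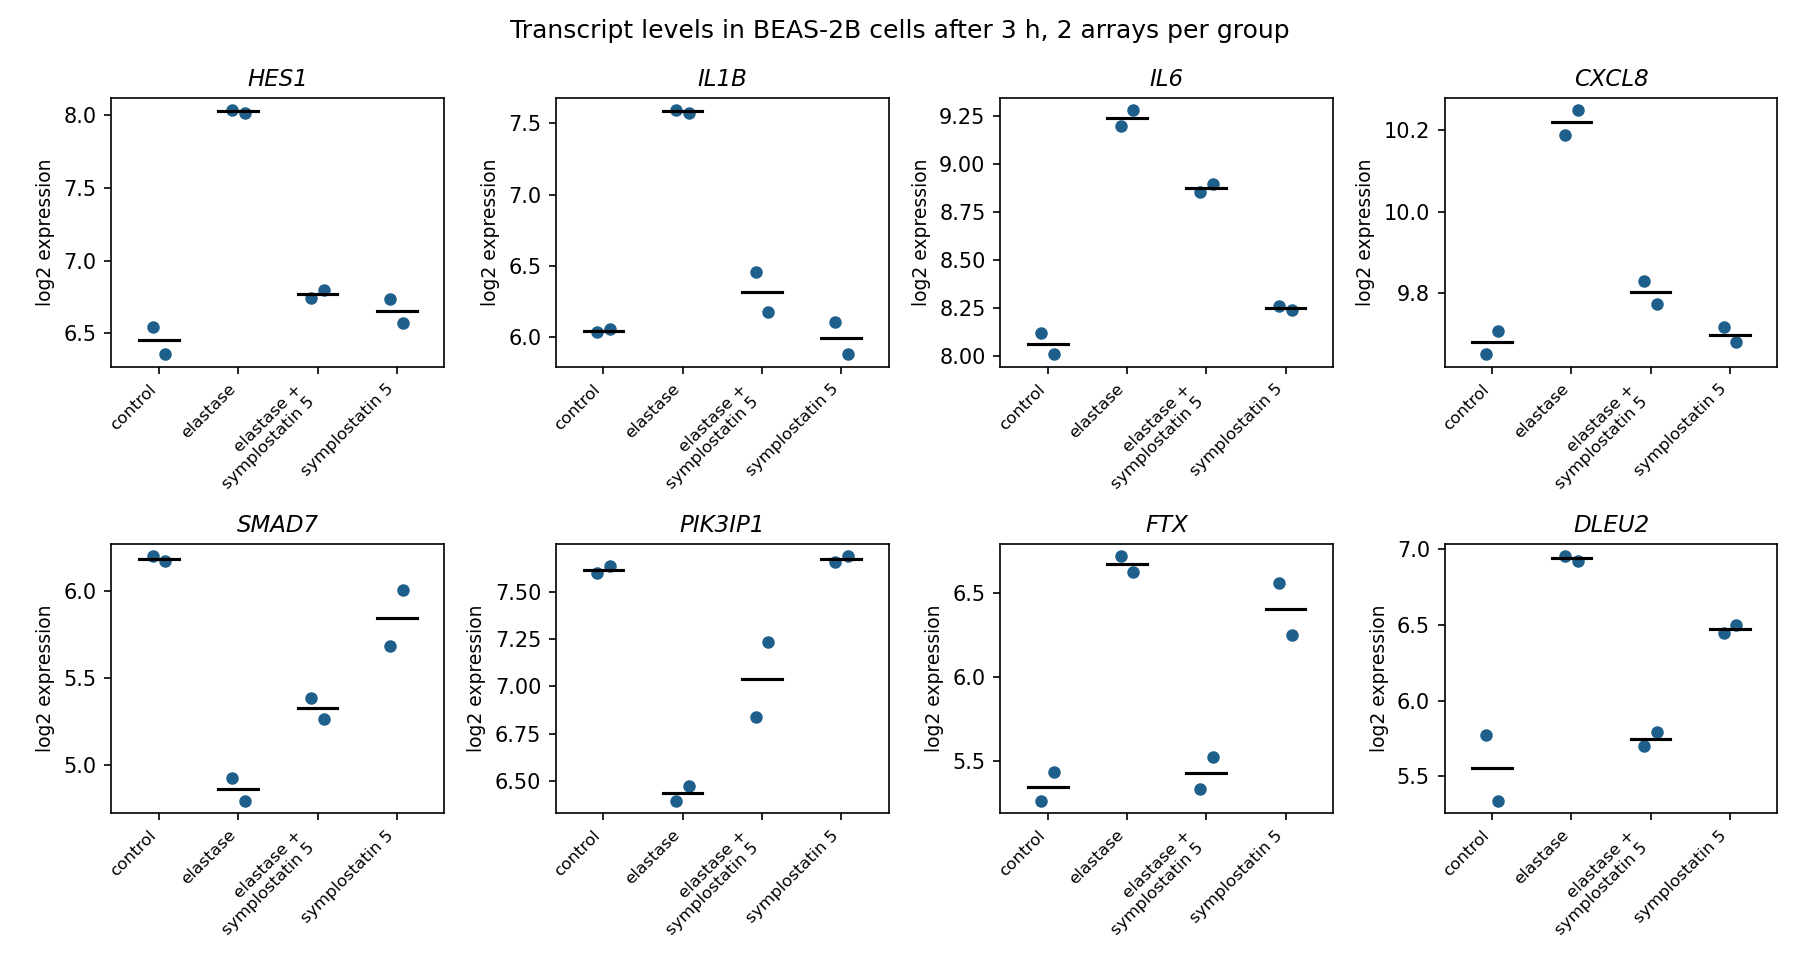
Log2 expression (y axis) of 8 genes in the 4 treatment groups (x axis); points are the 2 arrays of a group and lines their mean. The 2 elastase arrays lie apart from the 2 control arrays in each panel; HES1 and IL1B in the combination lie at means of 6.77 and 6.32, near their control means of 6.45 and 6.04, IL6 stays at 8.88 against 8.07, and FTX and DLEU2 are also high with symplostatin 5 alone.

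Among the genes that fell with elastase were 2 feedback repressors of TGF-beta signalling, SMAD7 with a log2 fold change of -1.33 (SE 0.12, limma adjusted p = 0.014) and SKIL with -0.96 (SE 0.093, adjusted p = 0.016). PIK3IP1, an inhibitor of PI3-kinase, changed by -1.18 (SE 0.13, adjusted p = 0.021) and the stress-response gene GADD45B by -0.96 (SE 0.092, adjusted p = 0.016). YPEL2, NEDD9, SERTAD4, APOLD1 and STARD13 fell by 0.90, 0.88, 0.86, 0.82 and 0.82 on the log2 scale. MYCN, a MYC family transcription factor, had the largest fall at -1.41, but only 4 of its 10 probe sets had that sign. For HES1, 2 of 3 probe sets went up, and both probe sets of IL1B did.

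Among the 10 largest rises were also the lncRNAs FTX (1.32, SE 0.13), DLEU2 (1.38, SE 0.14) and LOC100190986 (1.42, SE 0.19) and the pseudogene transcripts SMG1P5 (1.42), GTF2H2B (1.21) and RPS16P5 (1.17), all as log2 fold changes. Of 2657 lncRNAs tested 5 were called, of 497 pseudogenes 4, and of 16520 protein-coding genes 29; the lncRNAs and pseudogenes called were all higher, and of the protein-coding genes 15 were higher and 14 lower. Whether the classes differ was not tested. Pseudogene probes can also bind transcripts of the parent gene, so these 4 are uncertain. The 7 probe sets of DLEU2 ran from 0.0262 to 1.38, with 4 of them higher at an unadjusted p under 0.05 by limma. The 2 of FTX were at 0.495 and 1.32. ZNF750, an epidermal differentiation factor with the largest rise (1.85, SE 0.20), was a dim transcript with a mean of 2.73 over the 8 arrays.

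In all, limma called 38 of 19775 genes in elastase vs control, 24 higher and 14 lower, between 0.61 and 1.85 in absolute log2 fold change, and 2042 genes had an unadjusted p under 0.05 where 989 are expected by chance. The labels give biological duplicates, so the spread behind these p-values is one between separate samples. It was pooled over the 2 samples of each of the 4 groups and moderated over all genes, and is not that of control and elastase alone. The count rested on each array of the compared groups: it was 2 without control replicate 1, 0 without control replicate 2, and 0 without elastase replicate 1 or elastase replicate 2. It was 13 without either array of the combination, and 0 when only control and elastase arrays were fitted or values were floored at the 20th percentile. It was 2 at an adjusted p under 0.01 and 20 with the replicate number as a block. It rose to 87 with all probe sets tested, 140 with the upper 50% of genes by mean and 307 with eBayes' trend and robust settings. With the mean of a gene's probe sets it was 40, of which 21 were among the 38.

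Of the fixed list of cytokines and chemokines, IL1B, IL6, IL1A and CCL2 rose with elastase. Of 29 measured members, these 4 rose, 0 fell and 25 did not pass over all genes, 19 were above 0 and 10 below, and 8 rose when adjusted over the list alone, which adds CXCL8, CXCL2, LIF and CCL5. The neutrophil chemoattractants CXCL8 and CXCL2 had log2 fold changes of 0.54 (SE 0.077, limma adjusted p = 0.057) and 0.67 (adjusted p = 0.083). The list's median log2 fold change was 0.18 and camera's adjusted p was 3.1e-08, with an adjusted p = 0.15 with an estimated correlation. The NF-kappaB list had a median of 0.07 (camera adjusted p = 0.0028; adjusted p = 0.22 with an estimated correlation), with 0 of 27 members called over all genes and 3 adjusted over the list alone, IRF1, GCH1 and BCL2A1. ICAM1, an NF-kappaB target, had a log2 fold change of 0.07 (adjusted p = 0.85).

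Of the targets of FOXO transcription factors, which growth factor signalling through AKT keeps low, 4 of 22 measured members fell with elastase over all genes and 18 did not pass, and 11 fell when adjusted over the list alone. The 4 were PIK3IP1, YPEL2, IRS2 (-0.79, SE 0.086) and CCNG2 (-0.76, SE 0.091). The list's median was -0.28 and 20 of 22 members were below 0 (camera adjusted p = 1.1e-08; adjusted p = 0.24 with an estimated correlation). YAP and TEAD targets had a median of -0.07, with 19 of 23 members below 0 and GADD45B called (camera adjusted p = 0.014; adjusted p = 0.24 with an estimated correlation). The YAP targets CCN1 and CCN2 had log2 fold changes of -0.38 and -0.55 (limma adjusted p = 0.16 and 0.11), and the YAP list's camera adjusted p was 0.07 without elastase replicate 2.

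Of TGF-beta and BMP targets, ID3 rose (0.71) while SMAD7 and SKIL fell, and 21 of 24 did not pass. The list's median was -0.12 and camera's adjusted p 0.042, with an adjusted p = 0.40 with an estimated correlation. This call was lost when any of the 8 arrays was left out, at adjusted p between 0.058 and 0.12. Interferon response genes had a median of 0.08 (camera adjusted p = 0.0080; adjusted p = 0.37 with an estimated correlation), and genes of the unfolded protein and integrated stress response a median of 0.00 and a mean of 0.07 (camera adjusted p = 0.028; adjusted p = 0.24 with an estimated correlation), each with 0 members called over all genes. The interferon call was lost without control replicate 2 or elastase replicate 1 (adjusted p up to 0.16) and with fry (0.25). The stress call was lost without control replicate 1 or elastase replicate 1 (up to 0.13) and with the upper 50% of genes by mean (0.075). Markers of secretory and ciliated cells had a median of -0.20 and of basal cells -0.14 (camera adjusted p = 0.028 and 0.042; adjusted p = 0.24 for either with an estimated correlation), with 0 members called. The secretory call was lost without control replicate 1 or elastase replicate 1 (adjusted p up to 0.45), with fry (0.068) and with the upper 50% of genes (0.3), and the basal call without control replicate 2 or either elastase array (up to 0.20) and with quantile normalization (0.066).

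The other 19 lists had camera adjusted p between 0.083 and 0.89 in this comparison. Immediate early genes had a median of -0.03, and FOS and EGR1 had log2 fold changes of -0.03 and -0.10 (limma adjusted p = 0.98 and 0.74). EGFR ligands and ERK output had a median of -0.02, and HBEGF, an EGFR ligand, had 0.35 (adjusted p = 0.37). The p53 target CDKN1A and the mucin MUC1 had 0.02 and -0.08 (adjusted p = 0.96 and 0.86). Leukocyte, fibroblast and endothelial markers had medians of -0.05, -0.00 and -0.06, and reference genes -0.01.

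The next comparison asked what symplostatin 5 does to the response when it is given with elastase. HES1 was lower with the combination than with elastase alone, at 6.77 ± 0.041 against 8.03 ± 0.011 (mean ± SD, n = 2), a log2 difference of -1.26 (SE 0.099, limma adjusted p = 0.043). IL1B differed by -1.27 (adjusted p = 0.072), IL1A by -0.59 (adjusted p = 0.16), CXCL8 by -0.42 (adjusted p = 0.21) and IL6 by -0.37 (adjusted p = 0.25). FTX and DLEU2 differed by -1.24 and -1.19 (adjusted p = 0.075 for either). HES1 was the only gene limma called here, and 1898 genes had an unadjusted p under 0.05. The call was lost without either elastase array or either array of the combination (0 genes each), and the count was 2 without either control array and 4 without either symplostatin 5 array. It was also lost with quantile normalization, a fit on the compared groups, the replicate number as a block, the floor and an adjusted p under 0.01 (0 genes each). The count was 5 with the mean of probe sets, 15 with all probe sets, 18 with the upper 50% of genes and 65 with trend and robust settings.

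The 38 genes called with elastase lay closer to control in the combination: all 38 had the opposite sign in elastase plus symplostatin 5 vs elastase, 34 of them at an unadjusted p under 0.05. Both comparisons use the elastase arrays, and 100 simulated sets of unchanged groups gave 93.7% with the opposite sign and 53.9% also at an unadjusted p under 0.05, against 89.5% (34 of 38) here. The share of the elastase effect left, from differences that share no array, was 0.008 over the 38 genes. It ran from -0.18 to 0.11 with an array left out, and could not be computed without control replicate 2 or either elastase array. It was -0.051 with the mean of probe sets, -0.031 with trend and robust settings and 0.037 with quantile normalization. Against control in place of symplostatin 5 it was 0.37, but that shares the control arrays. Simulated sets without any elastase effect gave 0.5. That value takes the whole elastase difference as noise, so it does not say how much of the 0.37 comes from the shared arrays. By kind of gene, which was not tested, over the 29 protein-coding genes it was 0.24, over the 14 genes that fell 0.41, and over the 9 lncRNAs and pseudogenes -0.52. Over the 15 protein-coding genes that rose it was 0.11. Of the 38 genes, 22 had the same sign in both differences and 16 the opposite sign, protein-coding CBFA2T2 (0.93 and -0.34) among them. IL6 and CCL2 were 0.62 and 0.53 higher with the combination than with symplostatin 5 alone, against 1.18 and 0.92 for elastase alone vs control, and MYCN was 0.84 lower against 1.41 lower.

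**Figure D2:**
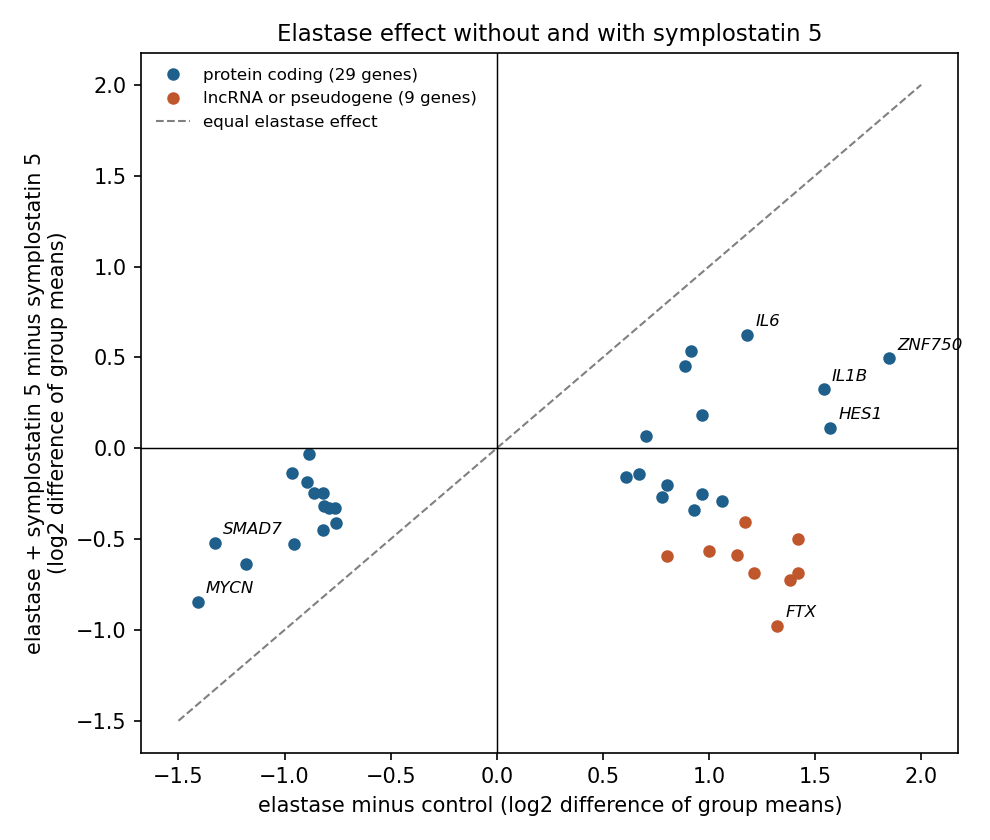
Log2 difference of group means between elastase and control (x axis) and between elastase plus symplostatin 5 and symplostatin 5 (y axis) for the 38 genes called in elastase vs control; each point is 1 gene, and the dashed line marks equal effects. The 29 protein-coding genes lie nearer to 0 on the y axis than the dashed line, with IL6 at 0.62 and MYCN at -0.84, and the 9 lncRNAs and pseudogenes lie below 0. Of the 38 genes, 16 have opposite signs on the axes, among them the protein-coding CBFA2T2 at 0.93 and -0.34.

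The interferon response list shifted lower in the combination than with elastase. Of 22 measured members 0 passed over all genes, 21 were below 0, and 6 fell when adjusted over the list alone: IFIT1, IFIT2, IFIT3, ISG15, OASL and IFI44, antiviral genes. IFIT2 and ISG15 had log2 fold changes of -0.42 and -0.39. The list's median was -0.16 (camera adjusted p = 1.8e-09; adjusted p = 0.23 with an estimated correlation). Cytokines and chemokines had a median of -0.16, and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 8.3e-07; adjusted p = 0.21 with an estimated correlation). These list calls held without each of the 8 arrays, but fry lost that of interferon genes (adjusted p = 0.053). The elastase arrays are shared with elastase vs control, and from the medians there unchanged groups would be expected at -0.04 for interferon genes and -0.09 for cytokines.

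Secretory and ciliated markers had a median of 0.18 in elastase plus symplostatin 5 vs elastase, against 0.1 expected of unchanged groups, with all 12 members above 0 and 0 called (camera adjusted p = 0.014; adjusted p = 0.27 with an estimated correlation). In this comparison the dimmer 2 of 4 bins of genes by mean signal had medians of 0.063 and 0.11. Extracellular matrix, hypoxia and NF-kappaB lists had medians of -0.04, -0.06 and -0.07 (camera adjusted p = 0.016, 0.034 and 0.048; adjusted p = 0.36, 0.36 and 0.31 with an estimated correlation), with 0 members called. The secretory call was lost without elastase replicate 1 or replicate 1 of the combination (adjusted p up to 0.19), those of matrix and hypoxia without elastase replicate 1 or either array of the combination (up to 0.27 and 0.19), and that of NF-kappaB without either elastase array or either array of the combination (up to 0.13). All 4 were lost with quantile normalization (0.067, 0.067, 0.09 and 0.14 in that order) and with the upper 50% of genes (0.26, 0.25, 0.38 and 0.4), and the first 3 with fry (0.077, 0.18 and 0.1). The other 22 lists had camera adjusted p between 0.065 and 0.96.

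The comparison of the combination with control asked what remained of the response. IL6 was 1.75-fold higher, at 8.88 ± 0.031 against 8.07 ± 0.080 (mean ± SD, n = 2), and MYCN was lower by a log2 fold change of -1.34, both at a limma adjusted p of 0.12. HES1 and IL1B had log2 fold changes of 0.32 and 0.27 (adjusted p = 0.52 and 0.60). limma called 0 genes, and 1652 had an unadjusted p under 0.05. With the upper 50% of genes 20 were called, and with trend and robust settings 53. All 38 genes called with elastase had the same sign in this comparison and a smaller size. The control arrays are shared, and simulated unchanged groups gave 97.4% with the same sign. The simulation already includes shared controls at the pooled spread, so an excess over it need not come from them. Over all genes the covariance of both sets of log2 fold changes was 0.0135 against 0.0080 in the simulation, and the correlation was 0.489 against 0.50. With elastase set against 1 control array and the combination against the other, the correlations were 0.086 and 0.14 and the covariances 0.0033 and 0.0051. These splits share no array, so their covariances do not come from a shared control array.

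The FOXO list shifted lower than control in the combination, with a median of -0.22 and 21 of 22 members below 0. Over all genes 0 fell, and 8 fell when adjusted over the list alone (camera adjusted p = 6.9e-10; adjusted p = 0.26 with an estimated correlation). EGFR ligands and ERK output had a median of 0.12, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 1e-04; adjusted p = 0.26 with an estimated correlation). EPHA2 and the ERK phosphatase DUSP6 had log2 fold changes of 0.57 and 0.45. Extracellular matrix and adhesion genes had a median of -0.11, with 27 of 31 below 0 (camera adjusted p = 1e-04; adjusted p = 0.26 with an estimated correlation). These list calls held without each of the 8 arrays. With fry those of ERK output and matrix were lost (adjusted p = 0.063 for either), and FOXO targets had 0.042. The low FOXO medians of all 3 treated groups rest on the same control arrays: from -0.28 with elastase, an unchanged group would be expected at -0.14. In comparisons without these arrays the list was not called, with a median of 0.039 in elastase plus symplostatin 5 vs elastase and -0.022 vs symplostatin 5 (camera adjusted p = 0.28 and 0.24). Unchanged groups would be expected there at 0.14 and 0.13. Medians near 0 would also arise if the targets fell alike in all 3 treated groups, so these comparisons do not decide the question.

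TGF-beta and BMP targets, interferon response, YAP targets, G2/M genes and SRF targets had medians of -0.10, -0.10, -0.11, -0.07 and -0.06 in the same comparison (camera adjusted p = 0.00058, 0.0020, 0.0054, 0.029 and 0.040; adjusted p = 0.26, 0.37, 0.26, 0.32 and 0.47 with an estimated correlation), with 0 members called over all genes. These calls were lost for TGF-beta targets without replicate 1 of the combination (adjusted p = 0.06), for interferon genes without control replicate 1 (0.07), for YAP targets without control replicate 2 (0.054), for G2/M genes without either control array or replicate 2 of the combination (up to 0.30), and for SRF targets without control replicate 1, replicate 2 of the combination or either symplostatin 5 array (up to 0.38). With quantile normalization those of YAP targets, SRF targets and G2/M genes were lost (0.051, 0.15 and 0.25), as they were with the upper 50% of genes (0.11, 0.11 and 0.16). With fry those of TGF-beta targets, interferon genes, G2/M genes and SRF targets were lost (0.063, 0.15, 0.063 and 0.15). The other 20 lists had camera adjusted p between 0.058 and 0.97.

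Symplostatin 5 alone vs control asked what the inhibitor does without added elastase. The lncRNAs FTX and DLEU2 were higher by log2 fold changes of 1.06 (SE 0.13) and 0.92 (SE 0.14), at a limma adjusted p of 0.083 for either, while HES1, IL1B and IL6 had 0.20, -0.05 and 0.19 (adjusted p = 0.29, 0.83 and 0.24). limma called 0 genes, though 4221 had an unadjusted p under 0.05 where 989 are expected by chance. The count was also 0 with quantile normalization (3586 at an unadjusted p under 0.05), array weights or a fit on the compared groups, 3 with the floor, 1610 with the lower-expressed genes left out, 529 with values centred on the median and 2009 with eBayes' trend and robust settings. Of the 4221, 1397 were higher and 2824 lower. The signal distributions of these arrays were the narrowest, and the median log2 fold change ran with mean signal: it was 0.055, 0.046, -0.080 and -0.096 from the dimmest to the brightest of 4 bins of genes, and between -0.027 and -0.0097 after quantile normalization.

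The list of ERK output genes shifted lower with symplostatin 5 alone, with a median of -0.26, and 12 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0052; adjusted p = 0.36 with an estimated correlation). SPRED1 and DUSP6, inhibitors of ERK signalling, had log2 fold changes of -0.56 and -0.54. FOXO targets had a median of -0.26, and 12 fell adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.36 with an estimated correlation). Hypoxia targets had a median of -0.13 with 20 of 21 below 0 (camera adjusted p = 0.0052; adjusted p = 0.36 with an estimated correlation). These list calls held without each of the 8 arrays. With quantile normalization, ERK output and FOXO targets had a camera adjusted p of 0.026 each, and hypoxia targets lost the call (0.18). With the upper 50% of genes ERK output had 0.049, and FOXO and hypoxia targets lost the call (0.18 and 0.25).

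The lists of proteases and their inhibitors, extracellular matrix, cytokines, YAP targets and G2/M genes shifted lower with symplostatin 5 alone, with medians between -0.17 and -0.13 (camera adjusted p = 0.0052, 0.0097, 0.025, 0.025 and 0.025; adjusted p = 0.36 for each with an estimated correlation) and 0 members called over all genes. Each of these 5 calls was lost without symplostatin 5 replicate 2 (adjusted p up to 0.083), those of cytokines, YAP targets and G2/M genes also without control replicate 2, and that of G2/M genes also without symplostatin 5 replicate 1. All 5 were lost with quantile normalization (0.075, 0.44, 0.065, 0.44 and 0.51 in the order given), which removes most of the shift with mean signal, and with the upper 50% of genes (0.25, 0.51, 0.55, 0.55 and 0.55). The other 20 lists had camera adjusted p between 0.052 and 0.97.

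Elastase plus symplostatin 5 vs symplostatin 5 gave the elastase effect in the presence of the inhibitor. The list of ERK output genes shifted higher, with a median of 0.38 and 15 of 25 members rising adjusted over the list alone (camera adjusted p = 9.5e-11; adjusted p = 0.13 with an estimated correlation). DUSP6, EPHA2 and PHLDA1 had log2 fold changes of 0.98, 0.86 and 0.75. Cytokines and chemokines had a median of 0.24 with 26 of 29 above 0, and IL6, LIF, CXCL6, IL1A and CCL2 rose adjusted over the list alone (camera adjusted p = 3.4e-07; adjusted p = 0.13 with an estimated correlation). Genes of the unfolded protein and integrated stress response had a median of 0.12, and DDIT4, ASNS, TRIB3, CHAC1 and PSAT1 rose adjusted over the list alone (camera adjusted p = 0.00092; adjusted p = 0.17 with an estimated correlation). These list calls held without each of the 8 arrays, but that of the stress response was lost with the upper 50% of genes (adjusted p = 0.081). The symplostatin 5 arrays are shared with symplostatin 5 vs control, and from the medians there unchanged groups would be expected at 0.13 for ERK output and 0.07 for cytokines. limma called 0 genes over all genes, with 2113 at an unadjusted p under 0.05, 11 called with the upper 50% of genes, 57 with trend and robust settings and 4 with the floor. Hypoxia targets had a median of 0.13 (camera adjusted p = 0.036; adjusted p = 0.46 with an estimated correlation), a call lost without replicate 1 of the combination or either symplostatin 5 array (adjusted p up to 0.18) or with quantile normalization (0.16) or the upper 50% of genes (0.12). The other 24 lists had camera adjusted p between 0.07 and 0.95.

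The interaction tested whether the elastase effect differed with and without symplostatin 5. HES1 had an interaction of -1.46 (limma adjusted p = 0.026), from an elastase effect of 1.57 without and 0.11 with symplostatin 5. FTX and DLEU2 had -2.30 and -2.10 (adjusted p = 0.026 for either). IL1B, IL6 and CXCL8 had -1.21, -0.55 and -0.44 (adjusted p = 0.099, 0.22 and 0.27). limma called 11 genes, all with a negative interaction, of which 6 were lncRNAs, 3 pseudogenes and 2 protein coding, and 2413 genes had an unadjusted p under 0.05. The count was 0 without control replicate 2, either elastase array, either array of the combination or symplostatin 5 replicate 1, 1 without control replicate 1 and 2 without symplostatin 5 replicate 2. It was 0 with the floor, at an adjusted p under 0.01 and with the replicate number as a block. It was 57 with the upper 50% of genes, 109 with all probe sets and 282 with eBayes' trend and robust settings. With the mean of probe sets it was 14, of which 6 were among the 11.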

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

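The tests of RNA degradation and of signal distributions below were chosen after their results were seen. The elastase effect differed with and without symplostatin 5 for 11 genes in limma's interaction contrast, named after their values were seen. With the mean of a gene's probe sets 6 of the 11 stayed called, and with the replicate block 0 genes were called. The interaction on the log2 scale was -2.30 for FTX, -2.10 for DLEU2, -1.90 for GTF2H2B, -1.71 for PSMD6-AS2, -1.58 for RPS16P5, -1.57 for SUZ12P1, -1.46 for HES1, -1.40 for LOC114224, -1.31 for CCDC18-AS1, -1.27 for CBFA2T2 and -1.18 for TAPT1-AS1. The count was 0 to 2 when any of the 8 arrays was left out, as the account of the interaction gives by array.

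Of the lists, 4 also differed by camera in the interaction. FOXO targets had a median interaction of 0.34 (camera adjusted p = 0.00046), ERK output genes 0.21 (0.00052), YAP targets 0.15 (0.024) and interferon genes -0.06 (0.031), and with an estimated correlation the adjusted p was 0.67 for each. The FOXO and ERK calls held without each array, but fry lost that of FOXO targets (adjusted p = 0.054). The YAP call was lost without control replicate 2, elastase replicate 2, replicate 1 of the combination or symplostatin 5 replicate 2 (adjusted p up to 0.099), with quantile normalization (0.21) and with the upper 50% of genes by mean (0.11). The interferon call was lost without control replicate 2, elastase replicate 1, either array of the combination or symplostatin 5 replicate 2 (up to 0.35), and with fry (0.37). The other 24 lists had camera adjusted p between 0.40 and 0.98.

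Probe sets with no single gene name, which the comparisons of genes do not use, were fitted separately. Of 13522 such probe sets, limma called 447 in elastase vs control, 438 higher and 9 lower. That is 3.3% of them, against 0.19% of genes, but these shares are not like for like. The 13522 were adjusted among themselves, which sets another cutoff on the unadjusted p, and each gene is held by 1 probe set. In symplostatin 5 vs control 352 were called, 316 of them higher, and in elastase plus symplostatin 5 vs control 0 were called, with 672 at an unadjusted p under 0.05. The combination vs elastase had 248 called, 236 of them lower and 12 higher, and the combination vs symplostatin 5 had 53, all lower. The interaction had 701 called, of which 685 were negative and 16 positive. The 438 had a median log2 fold change of 0.89 with elastase, 0.66 with symplostatin 5 and 0.19 with the combination, and 436 of them (99.5%) were above 0 in symplostatin 5 vs control. That comparison shares the control arrays, and 100 simulated sets of unchanged groups gave 88.3% above 0 and a ratio of medians of 0.52, against 0.75 here, so part of it may come from the shared controls. In elastase plus symplostatin 5 vs symplostatin 5, which shares no array with elastase vs control, 426 of the 438 were below 0, with a median of -0.478.

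The first pattern weighed is that of the 9 lncRNAs and pseudogenes called with elastase, out of 2657 and 497 tested. In elastase plus symplostatin 5 vs symplostatin 5, which shares no array with elastase vs control, all 9 were below 0, between -0.976 and -0.404. Of all 38 called genes, 16 had the opposite sign there, these 9 among them, and 22 the same sign. All 22 were among the 29 protein-coding genes, so the pattern held for some protein-coding genes but not for most. The share of the elastase effect left was -0.52 over the 9 and 0.24 over the 29. Protein-coding CBFA2T2 was at 0.59 in symplostatin 5 vs control and -0.342 in elastase plus symplostatin 5 vs symplostatin 5, and ANKRD13D at 0.711 and -0.288. Their probe sets differed in elastase vs control: the 5 of CBFA2T2 ran from -0.025 to 0.929 and the 3 of ANKRD13D from -0.14 to 1.06. Of these, 2 and 1 were higher at an unadjusted p under 0.05 by limma. The medians of the 9 were 0.91 in symplostatin 5 vs control (0 called) and -1.90 in the interaction. These comparisons share arrays with elastase vs control. The ratios in simulated unchanged groups, times the observed median of 1.21 with elastase, gave 0.64 and -1.26. That scaling takes the whole elastase difference as noise, so it does not say how much of 0.91 and -1.90 comes from shared arrays. Different signal distributions of the arrays are argued against as the whole cause, since after quantile normalization the median interaction was -1.86 (SD over genes 0.32), and the median in the comparison without a shared array was -0.62, against -0.6 before. RNA degradation, which would raise the 3' minus 5' difference of both ACTB and GAPDH, stays open because they disagreed. That of ACTB was -0.042 in the arrays of the single treatments relative to the other arrays (SD within groups 0.13), while that of GAPDH was 0.037 higher (SD 0.024). A larger share of nuclear RNA stays open too: 9 nuclear-retained lncRNAs outside the called genes had a median interaction of 0.096 (2 standard errors, 0.49), but they went both ways, with KCNQ1OT1 at -1.62 and MALAT1 at -1.45, and the list held transcripts also found in the cytoplasm. A response of the cells to each single treatment remains an untested possibility.

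The second pattern is the broad shift with symplostatin 5 alone, with 4221 genes at an unadjusted p under 0.05. Different signal distributions are argued against as the whole cause, since 3586 genes had such a p after quantile normalization where 989 are expected by chance. RNA degradation, which would raise the 3' minus 5' difference of both control genes, stays open because they disagreed. That of ACTB was -0.24 in symplostatin 5 relative to control (SD within groups 0.13), which goes against degradation. That of GAPDH was 0.048 higher (SD 0.024), which goes with it. An effect of the compound that is the same with and without elastase also stays open: 61.6% of these genes had the same sign in elastase plus symplostatin 5 vs elastase, which shares no array with it, between the shares set beforehand for and against it. Both comparisons had higher medians in dim than in bright genes, and what this adds to the share was not tested.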

How the results depend on the processing

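Fits without both symplostatin 5 arrays, the slope over protein-coding genes and the split estimate on the genes with the lowest p were added after seeing the data. The cause of the changes below was not tested, except that fits on fewer arrays have fewer residual degrees of freedom. Keeping the upper 50% of genes by mean gave 140 genes in elastase vs control, 20 in the combination vs control, 18 in the combination vs elastase, 1610 in symplostatin 5 vs control, 11 in the combination vs symplostatin 5 and 57 in the interaction. eBayes with trend and robust settings gave 307, 53, 65, 2009, 57 and 282 in the same order. Testing all probe sets gave 87 genes in elastase vs control (73 with a higher and 14 with a lower probe set), 15 in the combination vs elastase and 109 in the interaction. The mean of a gene's probe sets gave 40 in elastase vs control, 21 of them among the 38, and 5 in the combination vs elastase. In the interaction it gave 14, of which 6 were among the 11. Quantile normalization gave 0 in the combination vs elastase. Centring on the median gave 529 in symplostatin 5 vs control. A floor at the 20th percentile gave 0 in elastase vs control, 0 in the combination vs elastase, 0 in the interaction, 3 in symplostatin 5 vs control and 4 in the combination vs symplostatin 5. An adjusted p under 0.01 left 2 genes in elastase vs control, and 0 in the combination vs elastase and in the interaction. Fitting only the groups compared gave 0 in elastase vs control and 0 in the combination vs elastase. Without both symplostatin 5 arrays the counts were 32 in elastase vs control, 30 of them among the 38, and 4 in the combination vs elastase. With the replicate block the counts were 20 in elastase vs control, all among the 38, 0 in the combination vs elastase and 0 in the interaction. Deviations of arrays with the same number correlated between -0.189 and 0.0938 over all genes. This shows no strong pairing over all genes, but does not exclude a shared batch that moves some of them. The labels do not state whether the numbers mark a batch. Leaving out each array gave 0 to 32 genes in elastase vs control, 0 to 4 in the combination vs elastase, 0 to 2 in the interaction and 0 in the other comparisons. The lone array left in a group was then assumed to vary like the other groups. Of the 25 named genes called with elastase, 0 changed sign under the alternatives run, of which the filter on the mean held 21 of them, and log2 fold changes were at least 0.67 in absolute size with an array left out. With the mean of probe sets 16 stayed called, and the smallest was 0.06. The share of the elastase effect left, 0.008, was -0.051 with the mean of probe sets, 0.037 with quantile normalization, -0.031 with trend and robust settings, 0.044 with the replicate block, 0.37 against control in place of symplostatin 5 and 0.24 over protein-coding genes, and ran from -0.18 to 0.11 with an array left out. It could not be computed without control replicate 2 or either elastase array, or on the compared groups alone, which left 0 called genes. The planned split estimate was not run on called genes, since the fits without 2 arrays called 0; on the 38 genes with the lowest p it was -0.013. Of 39 list calls, 0 held with an estimated correlation, 25 with fry, 20 with the filter on the mean, 23 with quantile normalization and 38 with the replicate block, 29 to 35 held with an array left out, and 0 turned. In elastase vs control, median log2 fold changes in 4 bins of mean signal lay between -0.065 and -0.014, and in symplostatin 5 vs control between -0.096 and 0.055. In the combination vs elastase they were 0.063, 0.11, -0.019 and -0.019 from the dimmest to the brightest bin. After quantile normalization these lay between 0.0051 and 0.089. Low signal limits dim genes such as ZNF750.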

Other observations

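The test of Notch targets was chosen after the value of HES1 was seen. In this paragraph, the genes other than HES1 were picked after their values were seen, and 0 of them passed over all genes. Of genes that Notch signalling is known to induce, HEY1, a repressor related to HES1, had a log2 fold change of 0.75 (limma adjusted p = 0.096), HES4 0.83 (adjusted p = 0.095), and NRARP, a Notch feedback inhibitor, 0.51 (adjusted p = 0.18). In elastase plus symplostatin 5 vs symplostatin 5, which shares no array with elastase vs control, they were at 0.453, -0.0708 and -0.0317 (adjusted p = 0.36, 0.88 and 0.94). The ligand JAG1 had 0.27 with elastase (adjusted p = 0.39). HEYL and DTX1 went the other way, at -0.19 and -0.24.

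A hypothesis is that Notch target genes may move together with HES1 in cells treated with elastase. Over 14 targets other than HES1, 11 were above 0 with elastase, with a median of 0.27 (camera p = 9.5e-08; p = 0.018 with an estimated correlation). Most of these had been looked at before the list was written. The 4 whose values had not been, HEY2, DTX4, SOX9 and GATA3, had a median of 0.37 with elastase (camera p = 4.8e-05; p = 0.03 with an estimated correlation). The values fit the hypothesis in that comparison, though 4 genes are few and HEY2 and GATA3 are dim, with means of 3.49 and 2.99.

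Whether the 4 follow HES1 with the inhibitor is not shown by the combination vs elastase, which shares the elastase arrays: their median there was -0.09, and unchanged groups would be expected at -0.19. In elastase plus symplostatin 5 vs symplostatin 5, chosen after these values were seen, their median was 0.28 (camera p = 0.0051; p = 0.085 with an estimated correlation), while HES1 had 0.11 (adjusted p = 0.7). The median interaction of the 4 was -0.058, against -1.46 for HES1, so with the inhibitor the hypothesis stays open.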
